A study of Mus musculus with 18 samples.

How the data were processed

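Poly(A) RNA was measured in 18 libraries from primary mouse brain cultures, 3 replicates each of astrocytes, microglia and neurons and of the small extracellular vesicles (sEVs) from such cultures. Per the labels' protocols, RNA came from sEVs and from part of their source cells after on-column DNase treatment, cDNA was primed at poly(A) tails with a low-input kit and amplified with 15 PCR cycles, and libraries were made by tagmentation. That kit does not mark strand, so genes that overlap on opposite strands can share reads.

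The authors deposited 1 table of 54307 genes with a column of normalized counts (the signal values used here) per library and a column of means per group. Per the submitters' processing notes, reads were quantified with Salmon 1.8.0 against GRCm39 and normalized with DESeq2. The deposited signal values were checked for whole reads: dividing a library's values below 100 by its commonest non-zero value left 2.66 to 9.36% of them whole within 0.001. Raw counts could therefore not be recovered, no count model was run, and the reads per library are estimates, 30658287 to 77758633. Groups at 0 are given as listed at 0, without a fold, except Arc in the mean of the cell types, and where single libraries are at 0 a log2 value rests in part on the pseudocount. In 5 of the groups the deposited mean equals the mean of its 3 replicates, within 0.01 plus 0.01% of it. In the microglia sEV group it does so in 1477 of 18481 genes with any value, so the deposited means were not used.

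Differences were computed on log2 of the normalized count plus 1, in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend). One fit of all 18 libraries with 6 group means gave sEVs against cells in each cell type, their equal-weight mean, the pairwise differences between the types' sEV effects and an F test of these. Fits of the 9 cell and of the 9 sEV libraries gave the cell type pairs. Genes with a value of at least 10 in at least 3 libraries of a fit were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Log2 values are sEV minus cells, or the first named type minus the second, with the SE of the fit. Camera from the same package tested 35 gene lists of cell type markers, complexes and pathways with a preset inter-gene correlation of 0.01 and, beside it, an estimated one, adjusted over all lists and contrasts of a kind. List members were also adjusted over the list alone. Lists can share members: Ctsb, Ctsd and Cd63 stand in a lysosome list and in a list of microglia genes, and collagens in a matrix and a fibroblast list. Library measures were compared with two-sided exact permutation tests within each cell type and stratified over the 3 types. All groups, tests, lists and alternatives, except those named as added, were fixed before the data were examined.

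The genes named in the text were chosen by a fixed rule. For each comparison of sEVs with cells these were the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 50 in the higher group and no overlap between sEV and cell libraries (chance gives that to 10% of genes for 3 against 3 libraries), or the same sign in all 3 types for the mean. Symbols of predicted genes, RIKEN clones and pseudogenes were left out, 32 and 3 among higher and lower genes for the mean, 14 and 0 in astrocytes, 6 and 0 in microglia and 30 and 9 in neurons. Added were the 10 smallest p-values of the F test, up to 4 members of each list described by smallest p, the marker lists for cell type pairs, and Cd9, Cd63, Cd81, Tsg101, Pdcd6ip, Arc, Malat1 and Neat1. Within lists, Gfap, Aqp4, Dcx, Ifit2 and other members outside the smallest 4 p-values of that contrast were chosen after their values were seen.

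Genes are named by the symbols the table pairs with its Ensembl identifiers. The reference at hand was GENCODE vM21 on GRCm38, another build than the table's, so it served only for transcript length, GC content and shared sequence, and no coordinates are given. It held 19573 of the 19612 genes tested (99.8%). Transcripts were aligned with blastn 2.17.0 to 2 transcripts taken to be proviral, Gm42047 and Gm42427, at an expectation value of 1e-20. Their proviral origin was not tested against a viral or repeat reference, and proviral below means sequence shared with these 2. An alignment of at least 95% identity over at least 300 bases was called near-identical, and one below 90% distant.

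The tests were run on simulated data first. With 100 genes shifted by 1 log2 unit and 100 by 2 units, limma called 25% and 61% of them for the mean of the cell types, 13% and 35% in astrocytes, 9% and 25% in microglia, 5% and 32% in neurons, and 2% and 14% with the F test. For the cell pairs in the order of the text it called 17% and 65%, 31% and 71%, and 26% and 68%, and for the sEV pairs 0% and 3%, 0% and 5%, and 0% and 6%. At most 0.0735% of unchanged genes were called. The simulation changed far fewer genes than were called in the data and gave all groups the same mean per gene. The adjustment was therefore stricter than in the data, and these shares do not give the recovery of the real tests.

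The alternatives tried were pseudocounts of 0.5 and 5, no filter and a filter on a mean of 100, all libraries at the same total, quantile normalization, the replicate number as a block, library weights, a log2 threshold of 1, fits of only the groups compared, and each library left out in turn. Added after the data were seen were equal totals without Ftl1 and the proviral transcripts, and a fit without astrocyte sEV replicates 2 and 3. Genomic alignment, isoforms and strand were not examined, since no reads were at hand.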

Results

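Messenger RNA was sequenced from primary mouse cultures of astrocytes, microglia and neurons, and from the small extracellular vesicles (sEVs, membrane-bound particles that cells release) collected from such cultures. The 18 libraries fall into 6 groups of 3 replicates, cells and sEVs for each of the 3 cell types. The normalized counts of a library added up to between 36947428 and 69276566. An estimate of the reads behind them, from the commonest non-zero value of each library, ran from 41625666 to 77758633 in cells and from 30658287 to 53198032 in sEVs. The labels do not say whether the replicates of a group are separate cultures. The p-values of limma and of the library measures therefore reflect only the spread between these samples. Camera sets list genes against other genes, and a permutation test of solute carrier genes below exchanges genes, so neither measures the spread between cultures.

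The sEV libraries held fewer genes than the cell libraries, far less RNA encoded by the mitochondrial genome and more mRNA of cytosolic ribosomal proteins. At a value of 10 or more, astrocyte sEVs held 12760.0 ± 1248 genes and astrocyte cells 15847 ± 215 (SD, n = 3 each, as throughout). Microglia sEVs held 9255 ± 1229 genes against 13636 ± 157 in cells, and neuron sEVs 15626 ± 416 against 17636 ± 538. Mitochondrially encoded genes took 0.318% ± 0.202 of the astrocyte sEV total and 5.79% ± 1.15 of the cell total, and in neurons 0.317% ± 0.182 and 5.53% ± 0.567. In microglia these shares were 0.141% ± 0.0805 and 1.11% ± 0.157. Ribosomal protein genes took 3.15% ± 0.594, 2.05% ± 0.0827 and 8.08% ± 1.16 of the astrocyte, microglia and neuron sEV totals, and 1.08% ± 0.221, 0.840% ± 0.0753 and 1.15% ± 0.0303 of the cell totals. The 10 highest genes took 27.1% ± 4.61, 15.7% ± 0.559 and 25% ± 1.06 of these sEV totals, against 11.1% ± 1.34, 13.3% ± 0.611 and 7.64% ± 0.607 in cells. Every sEV library lay on the same side of every cell library of its type in each of these measures. A two-sided exact permutation test of 3 against 3 libraries gave p = 0.1 for each type, the smallest it can give. An exact permutation test that exchanged labels within the types, over all 8000 arrangements, gave p = 0.00025 for these measures, the smallest possible, with an adjusted p of 0.000292 over 7 measures. The share of the 100 highest genes, another of the 7, did not move in 1 direction: it was 40.0% ± 3.90, 40.7% ± 0.657 and 39.2% ± 0.685 in astrocyte, microglia and neuron sEVs and 30.5% ± 3.13, 42.1% ± 0.412 and 23.7% ± 0.206 in cells (adjusted p = 0.0065). Ftl1, the ferritin light chain and the highest gene of every sEV library, was singled out after its values were seen. It took 12.3 to 22.0% of the astrocyte, 3.96 to 5.0% of the microglia and 10.5 to 15.2% of the neuron sEV totals, and at most 1.41% of any cell library.

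**Figure D1:**
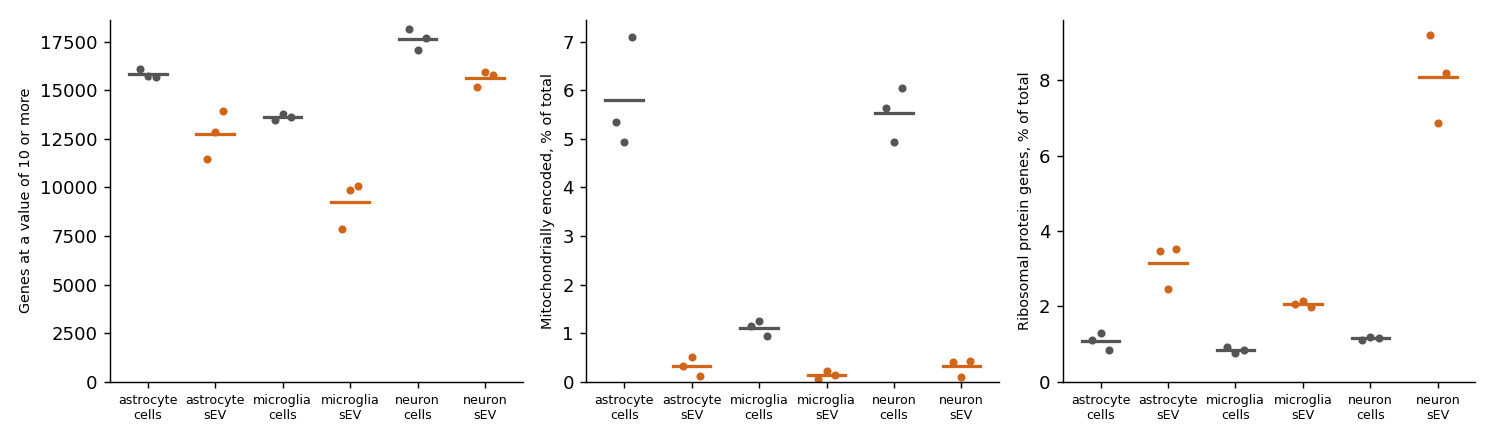
Genes at a normalized count of 10 or more, and the percent of each library's total in mitochondrially encoded and in cytosolic ribosomal protein genes, for 18 libraries in 6 groups. Points are libraries and bars are the means of 3, and the sEV points lie below those of their cells in the first and second panels and above them in the third.

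The comparison of sEVs with cells, averaged over the cell types with equal weight, asks which mRNAs differ in sEVs on average, and 1 or 2 types can carry such a call. The mRNAs of cytosolic ribosomal proteins, the protein parts of the ribosome, rose in sEVs: 85 of 90 were called higher and 0 lower (86 and 1 adjusted over the list alone). Rplp0 rose by 2.42 ± 0.05 in log2 units (SE), Rpsa by 3.25 ± 0.08 and Rpl13a by 2.69 ± 0.07. Translation factors rose in 22 of 38 members and fell in 9 (23 and 9 adjusted over the list alone), among them the elongation factors Eef1a1 (1.96 ± 0.05) and Eef2 (1.83 ± 0.09). Nuclear genes of oxidative phosphorylation rose in 53 of 75 and fell in 7 (56 and 7 over the list alone), with Atp5k at 2.05 ± 0.16, Uqcrq at 1.41 ± 0.11 and Sdha at -1.03 ± 0.06. All 15 mitochondrially encoded genes fell (15 over the list alone), with mt-Co1 at -4.15 ± 0.31. Of 34 lysosome genes 31 fell and 1 rose, the same over the list alone, with the protease Ctsb at -4.50 ± 0.15 and the saposin precursor Psap at -4.68 ± 0.19. Of 32 extracellular matrix genes 30 fell and 0 rose, the same over the list alone, including the collagens Col1a1 and Col6a1, which averaged 1212 ± 1015 and 533 ± 443 in microglia and were listed at 0 in astrocyte and microglia sEVs. Markers of fibroblast and meningeal cells, a list that shares collagens with the matrix list, fell in 20 of 20, and endothelial markers in 10 of 12 (20 and 10 over the list alone). Cholesterol synthesis genes fell in 16 of 24 and rose in 1 (17 and 1 over the list alone), with Msmo1 at -3.41 ± 0.20. Camera, which sets each list against all other genes, gave adjusted p-values of 2.52e-73 (ribosomal proteins), 5.14e-10 (translation factors), 4.65e-22 (oxidative phosphorylation), 1.92e-06 (mitochondrially encoded), 2.38e-12 (lysosome), 5.98e-06 (matrix), 0.000138 (fibroblast and meningeal), 0.0387 (endothelial) and 0.0112 (cholesterol). With an estimated correlation between genes in place of a preset one, the adjusted p-values were 0.145, 0.195, 0.364, 0.427, 0.168, 0.3, 0.416, 0.271 and 0.573 in the same order. None of the 52 list calls among 140 such tests of sEVs against cells held with that correlation. Ribosomal protein genes have many processed copies in the genome that can share reads, so single members are uncertain.

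Most genes whose proteins are used to mark sEVs had lower mRNA in sEVs than in cells or were not called. The tetraspanins Cd9, Cd63 and Cd81 were lower, at -4.01 ± 0.24, -2.93 ± 0.14 and -3.07 ± 0.15, and Pdcd6ip (ALIX) stood at -0.62 ± 0.16 (limma adjusted p = 0.00562, 0.114 with quantile normalization and 0.0599 at equal totals without Ftl1 and proviral transcripts). Tsg101 stood at -0.01 ± 0.10 (adjusted p = 0.941). Of the 30 genes on that list, 15 fell and 3 rose, the same over the list alone, and camera did not call it (adjusted p = 0.0835). Camera called it lower in astrocytes and neurons (adjusted p = 0.0305 and 0.00455), but with an estimated correlation the adjusted p-values were 0.177 and 0.145. There 10 and 11 of the 30 fell and 1 and 2 rose (13 and 12 lower, 1 and 2 higher, over the list alone). In microglia it was not called (adjusted p = 0.838). The nuclear noncoding RNAs Malat1 and Neat1 stood at -4.19 ± 0.21 and -3.25 ± 1.04. The neuronal gene Arc, whose protein forms capsids, stood at -0.01 ± 0.59 (adjusted p = 0.992), a value that rests in part on the pseudocount since Arc was listed at 0 in microglia sEVs.

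**Figure D2:**
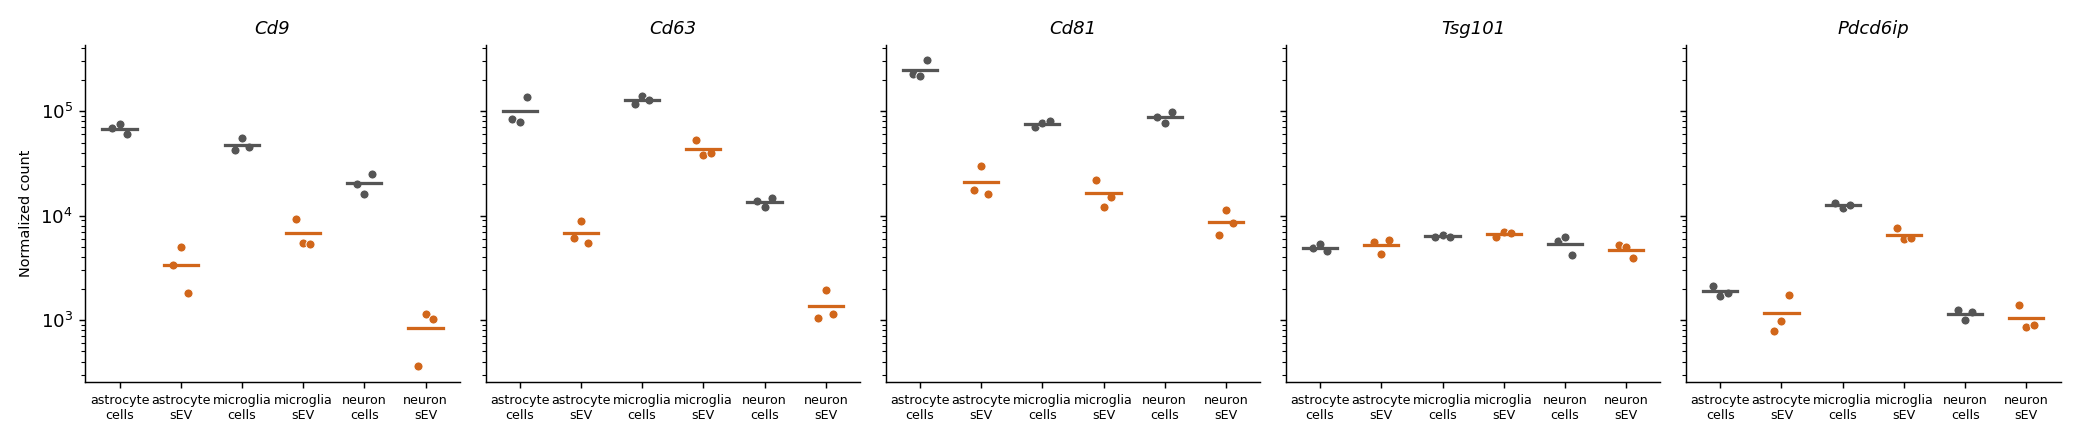
Normalized counts on a log10 axis of Cd9, Cd63, Cd81, Tsg101 and Pdcd6ip in 18 libraries. Points are libraries and short bars the means of 3, and Cd9, Cd63 and Cd81 lie lower in sEVs than in cells of every type while Tsg101 overlaps.

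Among genes named by the rule for the largest changes, Rcc2, a regulator of chromosome condensation, averaged 293164 ± 24524 in neuron sEVs and 1312 ± 266 in neurons. Over the cell types it rose by 5.51 ± 0.20. The transcription initiation factor subunit Taf10 rose by 4.97 ± 0.40, Cep85 by 4.96 ± 0.15, the transcription factor Sall3 by 4.77 ± 0.60, and the long noncoding RNA Lockd by 4.38 ± 0.35. AC102496.1 (9.0 ± 0.23), AC158975.2 (5.38 ± 0.24) and the chromatin remodeller Chd9 (4.30 ± 0.12) hold sequence near-identical to a proviral transcript, so their values are uncertain. AC160336.1 (5.97 ± 0.30), a distant relative of the proviral Gm42427 by sequence, and D6Ertd527e, listed at 0 in neurons, complete the 10. Among the 10 largest decreases, the peptide trimmer Erap1 of the endoplasmic reticulum averaged 1905 ± 969 in astrocytes and was listed at 0 in their sEVs. The secreted peptidase Cpq averaged 2887 ± 651 in microglia and was listed at 0 in their sEVs, and the transporter Slc7a4 averaged 7816 ± 290.4 in neurons and 126 ± 60.8 in their sEVs. The matrix protein gene Efemp1 averaged 514 ± 284, 530.0 ± 373 and 129.6 ± 64.5 in astrocytes, microglia and neurons and was listed at 0 in all 9 sEV libraries. Osmr, Manba, Mfsd9, Slc9a7 and Adora2b, each listed at 0 in the sEVs of 1 type or more, and Dock4 complete the 10. Of 19612 genes tested, limma called 9638, with 2355 higher and 7283 lower in sEVs. The median of all genes was -0.93, and quantile normalization of the log2 values moved it by 1.0 and gave 4711 higher and 4225 lower, so the balance of higher and lower calls depends on the scaling. The medians of the 9 lists with a camera p under 0.05 named above kept their sign with quantile normalization and with all libraries at the same total. Endothelial markers, however, fell in only 4 of 12 with quantile normalization, and their median moved from -3.08 to -1.34.

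In astrocytes, ribosomal protein mRNAs were again higher in sEVs and lysosome and matrix mRNAs lower. Ribosomal protein genes rose in 75 of 90 and fell in 0 (78 and 1 adjusted over the list alone), with Rplp0 at 2.53 ± 0.09 and Rpsa at 3.23 ± 0.14. Translation factors rose in 19 of 38 and fell in 6 (20 and 8 over the list alone), led by Eef1a1 at 2.26 ± 0.09. Lysosome genes fell in 29 of 34 and rose in 1 (the same over the list alone), with Laptm4a at -4.32 ± 0.23 and Psap at -4.93 ± 0.33. Matrix genes fell in 19 of 32 (24 over the list alone), with the secreted protein Sparcl1 at -4.88 ± 0.43. The astrocyte markers fell in 15 of 30 and rose in 0 (16 and 0 over the list alone). Among those markers the water channel Aqp4 averaged 7333 ± 2579.8 in sEVs and 125026 ± 27619 in cells, and the filament gene Gfap 459957 ± 162935 and 407058 ± 43694. Camera's adjusted p-values for these 5 lists were 1.84e-53, 6.47e-08, 4.86e-14, 6.1e-06 and 0.00455. With an estimated correlation the adjusted p-values were 0.161, 0.271, 0.161, 0.3 and 0.416. Nuclear genes of oxidative phosphorylation rose in only 11 of 75 and fell in 8 (the same over the list alone), with a median of 0.17. At equal totals 5 rose and 11 fell, with a median of 0.00503, and with quantile normalization 12 rose and 10 fell. Camera ranked that list above the other genes (adjusted p = 0.00584), but not with an estimated correlation (adjusted p = 0.783). Cd9, Cd63 and Cd81 stood at -4.44, -3.86 and -3.60 (SE 0.41, 0.25 and 0.25) and Malat1 at -2.72 ± 0.36. Not called were Tsg101 (0.07 ± 0.17), Pdcd6ip (-0.76 ± 0.28), Arc (1.63 ± 1.02) and Neat1 (-2.49 ± 1.81). Pdcd6ip was called without astrocyte sEV replicate 3 (adjusted p = 0.00563) or neuron sEV replicate 1 (0.0482), at equal totals (0.0365) and without astrocyte sEV replicates 2 and 3 (0.00808). Neat1 was called without microglia sEV replicate 1 (0.00315), with library weights (0.0396) and with only the 6 astrocyte libraries (0.0394). Of the largest increases, Rcc2 rose by 7.25 ± 0.34, and Gprin2, Gpr182, Trim66 and AC124108.1 averaged 857 ± 997, 214 ± 122, 232 ± 214 and 294 ± 229 in sEVs and were listed at 0 in cells. The macrophage pore protein Mpeg1 and the chemokine Ccl5, both abundant in microglia, averaged 359 ± 61.1 and 319 ± 170.4 in astrocyte sEVs. AC160336.1, the distant proviral relative, and the near-identical AC102496.1 and AC158975.2 complete the 10. Of the largest decreases, the endosomal RNA sensor Tlr3, Erap1, the matrix protein Fmod, the peptide transporter Tap2, Manba, Serpinf1, Gpc5 and Mfsd9 averaged between 889 and 2077 in astrocytes and were listed at 0 in the sEVs. The lipid transporter Mfsd2a stood at -10.63 ± 1.92 and the granin Chgb at -10.22 ± 1.84. Of 19612 genes, 5215 were called, 1569 higher and 3646 lower. With quantile normalization, which moved the median of all genes by 0.755, 2624 were higher and 2681 lower. Without astrocyte sEV replicates 2 and 3, a fit added after the values were seen, 5706 genes were called.

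In microglia, the mRNAs of ribosomal proteins and most nuclear genes of oxidative phosphorylation were higher in sEVs than in cells. Ribosomal protein genes rose in 79 of 90 and fell in 0 (80 and 0 adjusted over the list alone). Rplp0 stood at 1.01 ± 0.09 and Rpsa at 1.65 ± 0.14. Nuclear oxidative phosphorylation genes rose in 51 of 75 and fell in 3 (52 and 4 over the list alone), with Uqcrq at 1.40 ± 0.19 and Ndufa2 at 1.44 ± 0.20. Proteasome subunits rose in 11 of 31 and fell in 2 (13 and 3 over the list alone), Psmb6 by 1.04 ± 0.13. The median of 39 proteasome subunits, 0.36, lay inside the range of lists matched on length, GC content and mean value (-0.09 to 0.54). Actin and tubulin cytoskeleton genes rose in 11 of 31 and fell in 1 (11 and 2 over the list alone), Pfn1 by 0.84 ± 0.11. Lysosome genes fell in 25 of 34 and rose in 0 (26 and 0 over the list alone), and matrix genes fell in 21 of 32 and rose in 0 (23 and 1 over the list alone). The cholesterol exporter Npc1 averaged 2430.2 ± 282 in cells and was listed at 0 in sEVs, and the saposin precursor Psap stood at -4.67 ± 0.33. Camera's adjusted p-values for these 6 lists were 6.88e-59, 5.19e-27, 1.98e-07, 1.11e-05, 3.25e-12 and 0.000143. With an estimated correlation the adjusted p-values were 0.161, 0.292, 0.416, 0.271, 0.168 and 0.407. Fibroblast and meningeal, endothelial and mural markers also fell, in 16 of 20, 8 of 12 and 8 of 12, and rose in 0 (17, 9 and 8 lower over the list alone). Camera's adjusted p-values for them were 4.4e-05, 0.00683 and 0.031, and with an estimated correlation 0.407, 0.168 and 0.416. Whether these and the matrix mRNAs came from other cells in the cultures was not tested. Interferon response and inflammatory genes, high in these microglia, were not called as lists here. Among them Ifit2 averaged 621592 ± 61759.5 in sEVs and 663402 ± 19015 in cells, and the transcription factor Stat2 fell by 3.0 ± 0.42. Cd9, Cd63 and Cd81 stood at -2.86, -1.56 and -2.25 (SE 0.41, 0.25 and 0.25) and Malat1 at -5.73 ± 0.36. Neat1 stood at -6.10 ± 1.81 (adjusted p = 0.0213, and 0.0512, 0.0646 and 0.0527 without microglia cell replicates 1, 2 and 3 and 0.151 with only the 6 microglia libraries). Pdcd6ip stood at -0.94 ± 0.28 (adjusted p = 0.0226, and 0.0716, 0.0545 and 0.0636 without these and 0.0542 without microglia sEV replicate 2). Its call also ended with the replicate block (adjusted p = 0.0506), library weights (0.0918), equal totals (0.165), quantile normalization (0.159) and equal totals without Ftl1 and proviral transcripts (0.193). Tsg101 (0.07 ± 0.17) was not called, and Arc averaged 8.1 ± 14 in cells and was listed at 0 in sEVs. Of the largest increases, the centrosomal gene Cep85 averaged 1021128 ± 67826 in sEVs and 3868 ± 455 in cells, the second highest gene of microglia sEVs. Cnbd2 averaged 9380.4 ± 913 and 324 ± 156. Camk2b and Stmn4, expressed mainly by neurons, averaged 760.2 ± 133 and 302 ± 291 in these sEVs. Camera ranked the neuron markers above the other genes in microglia (adjusted p = 0.00496), but not with an estimated correlation (adjusted p = 0.457). Only 3 of 32 rose and 2 fell (2 and 1 over the list alone), with a median of 0 where that of all genes was -0.79. With quantile normalization 13 rose and 1 fell, and the median was 1.92. The median of blood markers moved from 0 to 1.92 too, so this move is not particular to neuron markers. Pantr1, Lockd, Sall3, Prdm10 and Plekhb1 rose by between 4.11 and 5.46, and AC102496.1 completes the 10. Of the largest decreases, Timp3, Cpq, Npc1, Lmf2, Serpinf1 and Ccn1 averaged between 2335 and 4874 in microglia and were listed at 0 in sEVs, and Zfyve27, Lrrc8c, Il17ra and Igf2r averaged at most 2.2. Of 19612 genes, 5147 were called, 996 higher and 4151 lower. Quantile normalization moved the median by 1.05 and gave 2957 higher and 2402 lower, and library weights estimated by limma gave 3384 calls.

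In neurons, ribosomal protein mRNAs were higher in sEVs than in cells, and the 10 largest decreases included neuropeptide and protocadherin genes. Ribosomal protein genes rose in 85 of 90 and fell in 0 (87 and 0 adjusted over the list alone), with Rplp0 at 3.73 ± 0.09 and Rpsa at 4.88 ± 0.14. Oxidative phosphorylation genes rose in 54 of 75 and fell in 3 (58 and 6 over the list alone), with Uqcrq at 2.20 ± 0.19 and Ndufb8 at 1.68 ± 0.15. Members of the translation factor list rose in 19 of 38 and fell in 10 (20 and 11 over the list alone). Its member Tpt1, the gene of the translationally controlled tumour protein, rose by 3.71 ± 0.18. Lysosome genes fell in 26 of 34 and rose in 0 (26 and 1 over the list alone), with Ctsb at -5.61 ± 0.27. Cholesterol synthesis genes fell in 10 of 24 (10 over the list alone), with Hmgcs1 at -2.66 ± 0.21. Matrix genes fell in 14 of 32 (16 over the list alone). Camera's adjusted p-values for these 6 lists were 8.02e-73, 1.02e-20, 2.18e-06, 3.6e-11, 0.00152 and 0.00105. With an estimated correlation the adjusted p-values were 0.145, 0.377, 0.329, 0.177, 0.477 and 0.427. Cd9, Cd63 and Cd81 stood at -4.74, -3.37 and -3.35 (SE 0.41, 0.25 and 0.25) and Malat1 at -4.11 ± 0.36. Not called were Tsg101 (-0.17 ± 0.17), Pdcd6ip (-0.16 ± 0.28), Arc (-0.10 ± 1.02) and Neat1 (-1.14 ± 1.81). Of the largest decreases, the prohormone convertase Pcsk1 and the neuropeptide Vip averaged 2396 ± 951 and 1076 ± 171 in neurons and were listed at 0 in their sEVs, as were Pcdha1, Pcdhga8, AC164106.1 and Smim43. The enkephalin precursor Penk stood at -8.91 ± 1.28, Gdf1 at -8.90 ± 1.58, Pcdhga3 at -8.97 ± 1.81 and Pcdhga11 at -8.86 ± 2.24. Clustered protocadherins share constant exons, so reads cannot always be assigned to one of them. Of the largest increases, Rcc2 rose by 7.82 ± 0.34, the zinc finger gene Zfp660 by 7.22 ± 0.50 and AC090479.2 by 8.82 ± 1.09. Lncenc1 and D6Ertd527e averaged 152 ± 49.1 and 211 ± 139 in sEVs and were listed at 0 in neurons. Mpeg1, Zbtb42 and AC160336.1 rose by 7.30, 6.62 and 7.14 (SE 0.86, 1.67 and 0.52), and AC102496.1 and AC158975.2 complete the 10. Of 19612 genes, 5890 were called, 2185 higher and 3705 lower. Quantile normalization moved the median by 0.545 and gave 3615 higher and 3439 lower, while a filter on a mean of 100, library weights estimated by limma and a fit of the 6 neuron libraries alone gave 3891, 9158 and 9383 calls.

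**Figure D3:**
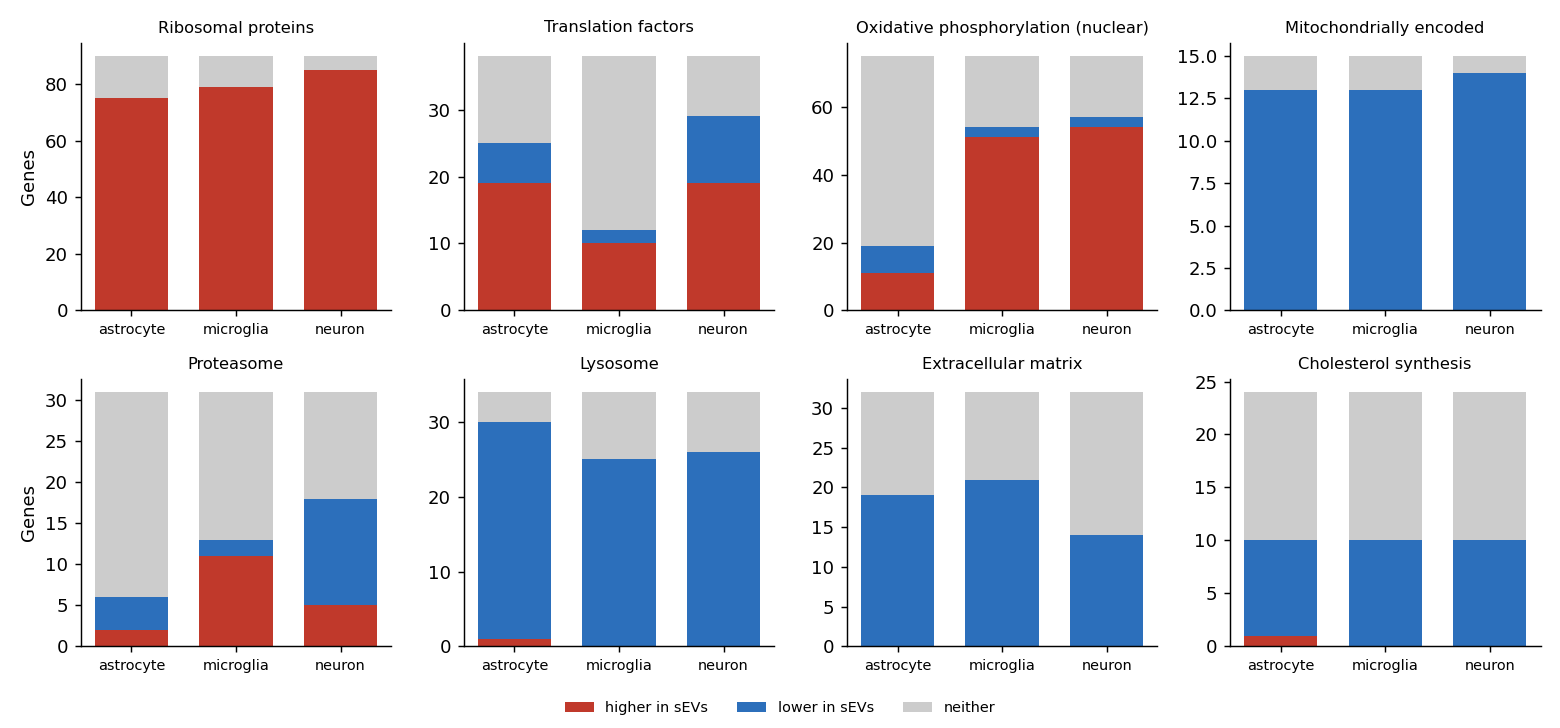
Number of members of 8 gene lists that limma called higher, lower or neither in sEVs than in cells, for astrocytes, microglia and neurons. Bars start at 0 and add up to the members tested, such as 90 ribosomal protein genes with 75, 79 and 85 called higher.

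The series design asks for packaging specific to a cell type, and the difference between the types' sEV effects was tested for it. A gene that a type hardly expresses has an sEV effect near 0 there by construction, so such genes reflect expression as well. Of the genes called by the F test 1539 (36.3%) stayed under a mean of 10 in cells and sEVs of at least 1 type, and 2695 did not, a count added after the result was seen. Ribosomal protein mRNAs differed most clearly: neuron sEVs gained more of them than astrocyte sEVs in 63 of 90 genes and less in 0 (78 and 0 adjusted over the list alone), and more than microglia sEVs in 66 and less in 0 (75 and 0 over the list alone). Oxidative phosphorylation genes gained less in astrocytes than in neurons in 35 of 75 genes and more in 1 (46 and 3 over the list alone), and less than in microglia in 17 and more in 2 (34 and 2 over the list alone). Its member Cox6a1 fell by 1.74 ± 0.18 in astrocytes and rose by 0.90 ± 0.18 in neurons. Proteasome genes gained more in microglia than in neurons in 14 of 31 and less in 1 (the same over the list alone). Camera's adjusted p-values for these 5 tests were 2.55e-54, 3.72e-29, 4.54e-21, 3.34e-11 and 3.15e-06, and with an estimated correlation the adjusted p-values were 0.308 for the first and 0.747 for the others. Of the 10 genes with the smallest F-test p, Rplp0 and Rpl9 averaged 412778 ± 21772 and 115017 ± 6709.9 in neuron sEVs against 67072 ± 5957 and 13490.5 ± 938 in microglia sEVs. Fam168b rose by 4.54 ± 0.15 in astrocytes and 4.88 ± 0.15 in neurons, and averaged 1984 ± 198 in microglia sEVs and 1412 ± 94.3 in microglia. AI506816, which shares sequence with proviral transcripts and is uncertain, rose by 4.80 and 5.44 in astrocytes and neurons and fell by 2.12 in microglia (SE 0.23 each). The neuropeptide Vip and the receptor Npy2r were detected only in neuron cells at 1076 ± 171 and 393 ± 85.9, and the ion channel Mcoln3 only in microglia cells at 1625 ± 456. Fat3, the glycan enzyme Glce and the fatty acid elongase Elovl6 averaged 785 ± 103, 790.3 ± 73.3 and 251 ± 37.1 in microglia cells and were listed at 0 in microglia sEVs, but averaged 2078 ± 479, 2029.8 ± 346 and 4726 ± 801 in neuron sEVs. The F test called 4234 of 19612 genes. In pairs, 2608 genes differed between astrocytes and microglia (1720 with the higher sEV effect in astrocytes), 999 between astrocytes and neurons (484) and 4069 between microglia and neurons (1533 higher in microglia). Of these, 1764, 608 and 2838 reached 10 in cells or sEVs of both types. Quantile normalization gave 1448 higher and 1331 lower, 592 and 402, and 2654 and 2351 for these pairs, and equal totals gave 1384 and 1475 for the first and 2270 and 1818 for the last. The astrocyte and neuron count was 567, 578 and 574 without neuron cell replicates 1, 2 and 3, 477 with a filter on a mean of 100 and 566 with the replicate block, and library weights estimated by limma gave 1699 for astrocytes and microglia.

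The genes called in one cell type were shared with the others more than independent lists would share them. Higher in sEVs of all 3 types were 460 genes and lower 901, where independent lists would share 8.88 and 146. Astrocytes and neurons shared 1221 higher and 1967 lower calls (175 and 689 if independent), astrocytes and microglia 522 and 1386 (79.7 and 772), and microglia and neurons 631 and 1171 (111 and 784). Called in opposite directions were 39, 152 and 230 genes for these pairs. The contrasts share 1 fit with 1 spread per gene, and the genes include some that a type hardly expresses. Calls can coincide for these reasons too, so independent lists are only a rough yardstick. Across genes, which are not independent replicates, Pearson's correlation of the log2 differences was 0.613 for astrocytes and neurons, 0.288 for astrocytes and microglia and 0.205 for microglia and neurons.

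The cell libraries were compared pairwise to see how far the cultures differ. Microglia markers were lower in astrocytes than in microglia in 29 of 29 genes (29 adjusted over the list alone), with the lysosomal Cd68 at 152212 ± 10733 in microglia and 88.6 ± 27.4 in astrocytes, and the pan-leukocyte Ptprc at 61108 ± 7576 in microglia and listed at 0 in the others. Interferon response genes were higher in microglia than in astrocytes in 30 of 30 and inflammatory genes in 27 of 28 (30 and 27 over the list alone), and against neurons in all 30 and 28 (the same over the list alone). The labels name no stimulation of the microglia and do not exclude one, so differences from microglia, in cells and in sEVs, can hold a state of these cultures as well as the cell type. Ifit2 averaged 663402 ± 19015 in microglia and 854 ± 57.8 in astrocytes, and the chemokine Ccl4 averaged 858648 ± 30245 in microglia and was listed at 0 in astrocytes. Neuron markers were higher in neurons than in astrocytes in 27 of 32 (30 over the list alone), with Stmn2 at 69038 ± 11352 in neurons and 25.4 ± 5.1 in astrocytes. Astrocyte markers were higher in astrocytes than in neurons in 21 of 30 and lower in 1 (23 and 1 over the list alone), with the connexin Gja1 at 221674 ± 56232 and 18178 ± 2546. Camera's adjusted p-values for microglia markers, interferon response and inflammatory genes between astrocytes and microglia were 3.39e-17, 2.48e-20 and 4.5e-20, and for neuron and astrocyte markers between astrocytes and neurons 3.19e-14 and 9.74e-12. They held with an estimated correlation, with adjusted p-values of 0.0132, 0.00982, 0.0043, 0.00982 and 0.0471. Neuron and astrocyte cultures held markers of each other: Gfap averaged 37808 ± 4498 in neurons, and the immature neuron gene Dcx 2030.5 ± 455 in astrocytes. In microglia cells Gfap averaged 3539.9 ± 4217, with a wide spread, and Dcx was listed at 0. Of 18410 genes, 11850 differed between astrocytes and microglia (8028 higher in astrocytes), 5981 between astrocytes and neurons (1916) and 13196 between microglia and neurons (3666 higher in microglia). Quantile normalization gave 5898 higher and 4840 lower, 4192 and 3155, and 5763 and 6043, and equal totals gave 10523 and 2619 for the first.

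Microglia and astrocyte markers differed between astrocyte and microglia sEVs, and some neuron markers between neuron and astrocyte sEVs. Between astrocyte and microglia sEVs, microglia markers were lower in astrocytes in 24 of 26 genes and higher in 1, and astrocyte markers higher in 20 of 29 and lower in 2 (24 and 1, and 24 and 2, adjusted over the list alone). The calcium-binding microglia gene Aif1 averaged 21423 ± 3248 in microglia sEVs and 1.9 ± 3.3 in astrocyte sEVs, and Gfap 1944 ± 755 and 459957 ± 162935. Interferon response genes were higher in microglia sEVs in 30 of 30 and inflammatory genes in 26 of 27 (the same over the list alone), with Mx1 at 32989 ± 2282 and Cxcl1 at 13589.9 ± 5427, both listed at 0 in astrocyte and neuron sEVs. Neuron markers were higher in neuron than in astrocyte sEVs in 11 of 30 (19 over the list alone), with Neurod6 at 1194 ± 127 in neuron sEVs and listed at 0 in the others. Ribosomal protein genes were higher in neuron than in astrocyte sEVs in 79 of 89 and lower in 0 (80 and 0 over the list alone). Camera's adjusted p-values in this order were 6.44e-14, 2.9e-05, 3.36e-20, 4.47e-17, 1.88e-07 and 5.85e-32, and with an estimated correlation the adjusted p-values were 0.149, 0.202, 0.094, 0.154, 0.247 and 0.202. Of 15514 genes, 6128 differed between astrocyte and microglia sEVs (4131 higher in astrocytes), 2309 between astrocytes and neurons (486) and 9131 between microglia and neurons (2106 higher in microglia). Of 14954 genes tested in cells and sEVs, 5195, 1403 and 7484 were called in both for these pairs, and 97.8, 99.1 and 97.1% of them had the same direction. Pearson's correlation between the cell and the sEV differences across genes was 0.790, 0.676 and 0.826. The astrocyte and neuron count fell to 452, 582 and 594 without neuron sEV replicates 1, 2 and 3, and to 1414 with a filter on a mean of 100. Quantile normalization gave 3068 higher and 2720 lower, 1146 and 1335, and 3536 and 3866 for these 3 pairs.

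Longer transcripts were lower in microglia sEVs, and GC-rich ones higher in neuron sEVs. Across 19573 genes, which are not independent replicates, Spearman's correlation of the log2 difference with transcript length was -0.183 in microglia, 0.0215 in astrocytes and -0.0202 in neurons, and -0.0784 for their mean. With GC content it was -0.0461 in microglia, 0.0411 in astrocytes, 0.191 in neurons and 0.0847 for the mean. Genes called higher in microglia sEVs had a median transcript length of 1939 bases and those called lower 3411 bases. The correlation with length in astrocytes turned negative without a filter and with quantile normalization, at -0.0778 and -0.0718.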

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

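The tests of the proviral pattern, except that on scaling, and the count of splits that set cells and sEVs of a type under the same label were chosen only after the results were seen.

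The effect of sEVs against cells differed between the cell types, in part in genes that 1 type hardly expresses. The F test called 4234 genes, and the pairwise tests called 2608 between astrocytes and microglia, 999 between astrocytes and neurons and 4069 between microglia and neurons. Among 100 splits of the libraries, the real one included, 2 gave as many genes for the F test, with 4833 as the highest other. That share is under 0.05, but the splits mix types that differ in many genes, and the median other split gave 0. A low share was thus largely built in, so it does not exclude chance for the F test. For the pairs, 5 of 100 splits gave as many for astrocytes and microglia (highest other 5222), 12 of 100 for astrocytes and neurons (5624) and 12 of 100 for microglia and neurons (13766), so the splits do not exclude chance there. The splits as large set the cells of one type against the sEVs of another, and their counts, up to several times the real ones, point to the difference between the cell types as a structure of the samples. In 86 splits for the F test, at least 5 of the 9 cell libraries had sEV libraries of their type under the same label. These gave at most 839 genes. For the pairs, 42, 37 and 42 splits met the same bound of 5 libraries and gave at most 37, 19 and 0. Such splits still mix types within a group, which widens the spread, so their low counts cannot decide on chance.

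For sEVs against cells averaged over the types, 1 of 100 splits, the real one, reached 9638 genes. The highest other gave 776 and the median other 0. The other splits mix cells and sEVs within a group, which widens the spread and lowers their counts. The share argues against a chance split of these libraries only. The labels do not say whether the replicates are separate cultures, so chance between cultures is not excluded. Within a type and between types, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, was as large in each case. The real counts were 5215, 5147 and 5890 in astrocytes, microglia and neurons (highest other 37, 76 and 34). For the pairs in cells they were 11850, 5981 and 13196 (highest other 0 each) and in sEVs 6128, 2309 and 9131 (highest other 2, 1 and 0).

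Transcripts near-identical to proviral sequence were raised in astrocyte and neuron sEVs, and to a lesser degree in microglia sEVs. Gm42047 and Gm42427, singled out after their values were seen, and their near-identical relatives together took 7.26 to 8.13% of astrocyte and 6.76 to 8.59% of neuron sEV totals. They took 0.101 to 0.182% of microglia sEV totals, 0.0116 to 0.0133% of microglia cell totals and at most 0.0345% of any cell library. Of the 13 relatives tested, 12, 13 and 7 were called higher in astrocytes, neurons and microglia. The 13 relatives tested had median log2 differences of 7.39 in astrocytes, 7.74 in neurons and 1.90 in microglia. In the same order, 16 distant relatives had -1.34, -0.28 and -0.92 and 12 relatives between these classes -0.25, 0.12 and -1.52. Reads of a few proviral RNAs spread over near-identical copies would give this, but so would a rise of each copy. The distant class had no minimum length and holds genes aligned over short stretches, such as Snhg17 (97 bases) and Lair1 (130 bases). Values of such genes could hardly follow proviral reads, so the comparison does not decide between the 2 readings. Of the distant relatives 1 in astrocytes and 3 in neurons were called higher, and AC160336.1, which aligns to Gm42427 at 69.6% identity, reached 8.88 and 7.14 there, so spread over near-identical copies does not cover every raised relative. Genomic DNA in the sEV libraries was tested first on the distant relatives, whose interval in neurons (-1.77 to 1.04) left it undecided. It was then tested on genes listed at 0 in cells, of which 2.19% in neurons and 1.94% in astrocytes reached 10 in sEVs. Their median stayed at 0, which argues against DNA at a level that shows in most genes. Sequence held in many copies could rise at a lower level of DNA, so DNA stays open for these transcripts. The neuron median was 7.44 at its lowest over both other scalings. Equal totals move all genes of a library alike, and quantile normalization moved the neuron median of all genes by 0.545. Neither could have brought 7.74 near 0, so the test was settled beforehand. It shows only that shifts of the size these scalings make are too small to account for the rise. That proviral RNA, in vesicles or in particles that were collected with them, may be released by astrocyte and neuron cultures stays open as an untested hypothesis. The proviral origin of Gm42047 and Gm42427 was itself not tested.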

How the results depend on the processing

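Equal totals without Ftl1 and proviral transcripts, and leaving out astrocyte sEV replicates 2 and 3 together, were chosen only after the data were seen. Of 184 values of counts and summaries under single alternatives other than leaving out 1 library, 160 stayed within 1.5 times their main count or within the replicate SD, 22 moved and 2 changed sign. The cause of a move was not tested unless stated. A filter on a mean of 100, with fewer genes tested, gave 3891 calls in neurons, 477 for astrocytes against neurons in the sEV effect and 1414 for their sEVs. Library weights gave 3384 calls in microglia, 9158 in neurons and 1699 for astrocytes against microglia in the sEV effect. A fit of the 6 neuron libraries alone gave 9383. With an estimated inter-gene correlation 0 of the 52 list calls held. Spearman's correlations without a filter were -0.214 with length for the mean, -0.0778 in astrocytes (reversed), -0.268 in microglia and -0.0772 in neurons, and 0.171 with GC content in neurons. With quantile normalization they were -0.159, -0.0718 (reversed), -0.219 and -0.0859 with length, and 0.109 for the mean and -0.00985 in microglia with GC content. With the filter on a mean of 100 they were 0.0368 for the mean, 0.00273 in astrocytes, -0.0774 in microglia and 0.175 in neurons with GC content.

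Leaving out each library in turn gave 567 to 1407 calls for astrocytes against neurons in the sEV effect, lowest without neuron cell replicate 1 (567) and also low without neuron cell replicates 2 (578) and 3 (574). The sEVs of these types gave 452 to 2557 calls, with 452, 582 and 594 without neuron sEV replicates 1, 2 and 3. The other counts stayed within 1.5 times: 8584 to 10107 for the mean, 3975 to 6069 in astrocytes, 3811 to 5760 in microglia, 4546 to 6777 in neurons and 3268 to 4854 for the F test. Without astrocyte sEV replicates 2 and 3 together, the lone library is assumed to vary like the other groups. For single genes, log2 differences near 0 changed sign in 27 cases, 3136 gave the same call, 15 lost it and 7 gained it. Arc for the mean was 0.20 with a pseudocount of 5, 1.24 with quantile normalization, 0.12 with library weights, 0.12 at equal totals without Ftl1 and the proviral transcripts, and -0.27 to 0.51 with a library left out. Arc in neurons was 0.58 with quantile normalization and -0.32 to 0.0217 with a library left out, and Pdcd6ip in neurons 0.15 with quantile normalization. Tsg101 for the mean was 0.0713 with quantile normalization, 0.0106 with library weights, 0.19 at equal totals without Ftl1 and the proviral transcripts, 0.0219 without astrocyte sEV replicates 2 and 3, and -0.0654 to 0.0367 with a library left out. Tsg101 in astrocytes was -0.10 at equal totals and -0.0232 to 0.21 with a library left out.

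The labels give cells and sEVs the same replicate numbers, and the protocol names shared source cells. Correlations between same-numbered libraries, as deviations from their group means, ran from -0.0396 to 0.0445 over 9 pairs. Astrocyte cell replicates 2 and 3 and microglia cell replicate 1 correlated better with sEVs of another number. The other cell libraries correlated best with their own number, in neurons at 0.00923, 0.0425 and 0.0445. These small values leave pairing open, and the fit without a replicate block, fixed beforehand, was kept. With the replicate block, calls were 9086 for the mean, 4477 in astrocytes, 4503 in microglia and 5232 in neurons, and 566 for astrocytes against neurons in the sEV effect. With 3 libraries per group, shifts of 1 log2 unit were recovered in at most 25% of simulated genes when sEVs were compared with cells. Far fewer genes were changed there than were called in the data, so this share does not give the recovery of the real tests.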

Other observations

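The tests of the microglia transcripts in astrocyte sEVs, the genes they run on, and the test of length and GC content in integrins and protocadherins alone were chosen only after the result was seen.

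Within several lists that were not called as a whole, members moved apart. Chaperones fell in 10 of 23 genes and rose in 4 (10 and 5 adjusted over the list alone; camera adjusted p = 0.47) over the mean of the cell types. The chaperones of the endoplasmic reticulum Hspa5 and Hsp90b1 stood at -4.30 ± 0.16 and -4.22 ± 0.23, and the cytosolic Hspa8 at -1.11 ± 0.05. Glycolysis genes fell in 13 of 22 and rose in 5 (14 and 5 over the list alone; adjusted p = 0.324), among them Hk1 at -2.26 ± 0.29 and Pkm at -0.82 ± 0.10. Of 32 core spliceosome genes 11 rose and 12 fell (the same over the list alone; adjusted p = 0.177): the small Lsm6 and Lsm7 rose by 1.53 ± 0.14 and 1.22 ± 0.11, and Sf3b1 and Snrnp70 stood at -2.17 ± 0.13 and -1.90 ± 0.17. Immediate early genes rose in 5 of 28 and fell in 8 (the same over the list alone; adjusted p = 0.254), with Ier5 at 2.48 ± 0.24 and Junb at -5.11 ± 0.74. With quantile normalization the higher and lower genes were 7 and 9 for chaperones, 5 and 13 for glycolysis, 13 and 12 for the spliceosome and 8 and 6 for immediate early genes. The medians of the last 2 lists turned, from -0.12 to 0.22 and from -0.37 to 0.81.

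Lists of synapse genes, genes derived from retrovirus-like capsids and RNA-binding protein genes were not called as a whole. Presynaptic genes rose in 2 of 31 and fell in 11 (1 and 11 adjusted over the list alone; camera adjusted p = 0.846), with the membrane fusion factor Nsf at -2.26 ± 0.20. Postsynaptic genes rose in 5 of 28 and fell in 9 (the same over the list alone; adjusted p = 0.803), and the glutamate receptor subunits Gria3 and Grin1 averaged 19609 ± 1014 and 1808 ± 544 in neurons and 1212 ± 374 and 62.4 ± 35.8 in their sEVs. Among 20 genes derived from capsids 1 rose and 5 fell (0 and 3 over the list alone; adjusted p = 0.718). Peg10, whose protein can carry its own RNA out of cells, averaged 2182 ± 313 in neuron sEVs and 108 ± 48.3 in neurons, and Rtl1 5.3 ± 9.1 and 67.5 ± 28.7. RNA-binding protein genes rose in 15 of 55 and fell in 22 (the same over the list alone; adjusted p = 0.441), with the cold-shock protein Ybx3 at 2.35 ± 0.17 and the splicing factor Srsf2 at -2.47 ± 0.17. With quantile normalization the higher and lower genes were 5 and 8 for presynaptic, 9 and 7 for postsynaptic, 5 and 0 for capsid-derived and 16 and 20 for RNA-binding protein genes, and the capsid median turned from -0.67 to 0.57. Ferritin heavy chain Fth1, singled out after its values were seen, rose by 2.28, 0.90 and 2.65 in astrocytes, microglia and neurons (SE 0.16 each).

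Abundant microglia transcripts had low values in astrocyte sEV replicates 2 and 3: of 50 genes high in microglia sEVs, 38 and 46 were above 0 there and 16 in replicate 1, at a median of 0.154% and 0.162% of the microglia sEV level and 0 in replicate 1. Ccl4 stood at 1366 and 1236 in replicates 2 and 3 and was listed at 0 in replicate 1 and in astrocyte cells, while Ccl5 stood at 134 in replicate 1 and at 469 and 356 in replicates 2 and 3. In neuron sEVs 17 to 25 of the 50 genes were above 0. Of the same genes 31, 28 and 30 were above 0 in astrocyte cell replicates 1, 2 and 3, and 26 to 30 in neuron cells. Microglia in the astrocyte cultures and carry-over of reads from the microglia sEV libraries cannot be told apart. For the first, the median in astrocyte cell libraries was at most 0.015% of the microglia cell level, far below the share in the sEVs, but few microglia could release many vesicles, and the bound set for this test was not passed by more than the spread of the cell libraries. For the second, the rank correlation with microglia sEV values minus that with microglia cell values was 0.076 in replicate 2 (interval -0.126 to 0.281) and -0.068 in replicate 3 (-0.293 to 0.151).

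As a group, 565 genes of solute carriers, transmembrane proteins, integrins, collagens and protocadherins were lower in sEVs than in cells, with medians of -2.63, -2.28 and -2.15 in astrocytes, microglia and neurons. Most of them were not called singly: 220, 198 and 193 were called lower and 13, 8 and 20 higher, beside 3646, 4151 and 3705 lower of all 19612 genes. For the 565 genes together, transcript length or GC content is argued against as the whole cause, since lists matched on these and on mean value had medians of -0.76, -1.10 and -0.49, and the family medians lay below the lowest 2.5% of them by at least 0.91 (-0.91). It stays open for integrins in astrocytes and neurons and for protocadherins in microglia, whose medians lay inside the matched range, at most 1.24 above its lowest 2.5%. Scaling was tested on the gap between ribosomal protein and lysosome medians, which was 5.07, 3.92 and 5.97 in astrocytes, microglia and neurons. With quantile normalization it was at least 3.31. That normalization moved the medians of all genes by 0.755, 1.05 and 0.545, and equal totals can hardly move such a gap. Neither could have closed it, so the test was largely settled beforehand. It shows only that shifts of this size are too small to account for the gap. The 565 genes themselves were not tested under other scalings. A candidate explanation is that translation at the endoplasmic reticulum keeps mRNAs out of sEVs, so that mitochondrial carriers (Slc25), made on free ribosomes, would be less depleted than other Slc genes. The Slc25 medians were higher by 1.54, 1.29 and 1.90 in astrocytes, microglia and neurons (two-sided permutation test over 45 and 227 genes with 100000 resamples, p = 0.00749, 0.0776 and 9e-05), which leaves the hypothesis open because microglia missed the threshold.

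The deposited mean of the microglia sEV group did not match its replicates. Taking replicate 3 from the neighbouring gene of the table gave that mean in 54306 of 54307 genes. Replicate 3 itself stands in place: over 9132 genes its Spearman correlation with replicate 1 was 0.768 as deposited and 0.0389 when moved to the neighbouring gene. Of these genes, which have a mean of at least 100, the deposited mean was off by more than 10% in 8084 and by more than 1.5-fold in 4405. For Cep85 the column gives 706729, where the replicates average 1021128.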
